A study of Homo sapiens with 6 samples.

How the data were processed

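The data are 6 libraries of Huh7 cells, 3 treated with DMSO and 3 with 16'-DEC for 24 h, grouped by their titles. Per the labels' protocols, RNA was extracted with a kit, poly(A)-selected with oligo(dT) beads, fragmented, reverse-transcribed with random primers and amplified by PCR; no strand marking is described. The authors deposited 1 table of TPM values, in which every library has the same sum, to within rounding, over 78304 genes, 35914 of them without a symbol. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the build GRCh38, without role or order; the annotation and the gene lengths behind TPM are not given in the sources used here. TPM are relative: a change in abundant genes shifts all others, and absolute depth cannot be recovered. Steps between values from 0.05 to 1 TPM gave only the reads behind 1 TPM relative to DMSO replicate 1. These equal relative depth only where the mix of transcript lengths is alike. No pair of libraries shared more than 0.0692% identical values among genes of at least 1 TPM, so none was counted as a duplicate.

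Genes with a mean of at least 1 TPM over the 6 libraries (14275) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05; all adjusted p-values of single genes are from this fit unless an adjustment is named. The scale understates changes of low genes. Without stated strand use, reads of overlapping and antisense genes cannot be told apart. Of 54 gene lists fixed before the data were examined, 51 with at least 5 measured members were tested with camera (preset correlation 0.01) and adjusted over lists; an estimated correlation, fry and ranks were alternatives. The named genes were fixed by rule: the 12 largest changes each way among called genes with a mean of at least 5 TPM, a symbol and no overlap between groups; per list, up to 4 members of smallest adjusted p in the majority direction and up to 2 in the other, or the 2 most abundant where none passed; 14 genes named in advance; and the 5 most abundant genes. This gave 311 genes, all of which were followed through the alternatives. The text names those of each list in the order of the rule, usually the leading pair, or in the closing section the leading member, and the leading member of the other direction; where that member was named for another list, the next is given. Some genes of the rule are not reported here.

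Transcript GC content and length came from GENCODE 29 on GRCh38 (per gene 1 transcript: APPRIS principal first, then basic, then the longest), matched by gene identifier for 93.1% of tested genes; coordinates are from the same annotation. The GC and length adjustment removed from each library a natural spline (5 degrees of freedom each) of its deviations on GC content and log2 length. The fit had an intercept, so it also re-centred the mean of each library, as a change of scaling does. Other alternatives, fixed at the same time as the lists, were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, no mean trend, array weights, the replicate number as a block, a threshold of 0.01 and leaving out each library. The fit was tested on simulated data with 200 changed genes among 13291: it recovered 71.6%, 98.5% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale and called 0.122% of unchanged genes. The changed genes all had a fitted DMSO level above 2 on the log2(TPM + 1) scale. Noise was normal, independent between genes and drawn with the variances of the same fit. In the data 71.5% of tested genes were called, so these rates do not show how the fit performs on these libraries. With a GC trend like the observed one, 56.9% of unchanged genes were called before the adjustment and 0.122% after it. That trend was drawn from the same spline on GC content that the adjustment removes, so its removal was fixed in advance. It does not show how the adjustment treats a real bias or a real effect that goes with GC content. A simulated list shifted by 0.5 was called with a preset (adjusted p = 5.82e-52) and an estimated correlation (adjusted p = 0.00338). Its noise was independent between genes and it held no GC trend, while the same list, proteasome subunits, had an estimated correlation of 0.156 in the data. The simulation therefore does not show how either list test performs on these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.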

Results

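Messenger RNA was measured by poly(A) RNA sequencing in Huh7 cells, an established line from a human hepatocellular carcinoma. Cells seeded for 24 h received the compound 16'-DEC or its vehicle DMSO for a further 24 h, and each group held 3 libraries. The compound is known here only by this code, and its dose is not given in the labels. The study's title concerns autophagy and liver cancer, so genes of both were among the lists fixed for the comparison. Values are TPM (transcript abundances scaled to a fixed sum), which carry no absolute depth. Steps between low values gave the reads behind 1 TPM relative to DMSO replicate 1 as 0.936 and 1.25 in the other DMSO libraries, and as 1.46, 1.58 and 1.53 with 16'-DEC. In the treated libraries 13319 ± 169 genes reached 1 TPM, against 15032 ± 91.4 in DMSO (mean ± SD, as for all levels given, 3 libraries per group). Mitochondrially encoded genes took 12% ± 1.13 of TPM in DMSO and 11.5% ± 0.223 with 16'-DEC (exact permutation p = 0.5, 2-sided, smallest possible 0.1). Libraries correlated across genes at 0.982 to 0.989 within DMSO, 0.99 to 0.994 within 16'-DEC and 0.898 to 0.922 between the groups (Pearson's r). The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries.

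The comparison asked which transcripts differed after 16'-DEC, as the study set out to learn how the compound acts on liver cancer cells. Genes of cell division were among those that fell most. CDK1, the kinase that drives entry into mitosis, fell from 282 ± 14.2 to 26.5 ± 0.554 TPM, and CENPF, a kinetochore protein, from 45.1 ± 3.3 to 3.05 ± 0.299 TPM. The changes were -3.36 ± 0.0703 and -3.51 ± 0.0968 on the log2(TPM + 1) scale (± SE, adjusted p = 1.03e-07 for both, limma), and -1.92 and -2.30 after an adjustment for GC content and transcript length. CDK1 (ENSG00000170312, chromosome 10, 60778331 to 60794852; GRCh38, GENCODE 29, as for all positions), CENPF (ENSG00000117724, chromosome 1, 214603195 to 214664588) and every gene named by size of change in this paragraph had no overlap between the libraries of the groups, because the rule that named them required this. KIF20B, SMC4, CENPK, HMMR, SGO2, RAD51AP1 and CENPE, which act in chromosome segregation or DNA repair, had changes from -3.31 to -3.10. CHST9 fell by 3.10, ESF1 by 3.08 and CCDC88A by 3.06. After GC adjustment the genes from KIF20B on were at -1.78 to -1.42. The largest increase among genes with a mean of at least 5 TPM was that of HSPA6, an inducible heat shock protein, listed at 0 in 2 DMSO libraries and at 0.109 TPM in the other, and at 9.0, 10.4 and 10.7 TPM with 16'-DEC. LGALS1 (galectin-1; ENSG00000100097, chromosome 22, 37675608 to 37679806) rose from 192 ± 26.3 to 1038 ± 59.7 TPM, AKR1C1, an aldo-keto reductase, from 1146 ± 88.9 to 5326 ± 123 TPM, and CDA (cytidine deaminase) from 17.1 ± 1.7 to 98.5 ± 2.92 TPM. SFN (14-3-3 sigma) rose by 2.16, C19orf33 by 2.32, HSPB8, a small heat shock protein, by 2.24 and LYPD3 by 1.94 (adjusted p from 1.17e-07 to 8.36e-06 for these and the preceding genes from LGALS1 on). The 5S ribosomal RNA genes RNA5S1, RNA5S5 and RNA5S15 each went from 1.86 ± 2.18 to 16 ± 7.57 TPM with identical values in every library. Over the fits without 1 library their change ran from 2.16 to 3.36. They are near-identical copies, and their levels are uncertain. AKR1C1 has close paralogs too, so reads could be shared between them.

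Of 14275 genes tested, 3236 were higher and 6974 lower with 16'-DEC, and at least 2-fold 375 were higher and 3378 lower. In 75.3% of tested genes the groups did not overlap, where chance gives 10%. The direction depended on scaling: the median gene changed by -0.31, and median-of-ratios scaling raised this by 0.29 and quantile normalization by 0.41. Lower genes made up 68.3% of calls as deposited (6974 of 10210), 50.4% with median-of-ratios scaling (5290 higher, 5376 lower) and 44.2% with quantile normalization (5990 higher, 4748 lower). The first of these scalings centres the median ratio and the second gives every library the same distribution. A more even split therefore follows largely from their construction and does not settle the direction.

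Fold changes also followed the GC content of the transcripts. Genes with a GC content under 40% had a median change of -1.46 (1842 of 1971 fell and 21 rose), and those over 60% had a median of 0.27 (254 of 2002 fell and 937 rose). Across protein-coding genes, which are not independent replicates, Spearman's rho was 0.705, and GC content accounted for 54.7% of the variance in fold change. An adjustment for GC content and transcript length, chosen after seeing the data, left 4590 genes higher and 4213 lower. The adjustment also re-centred each library, so part of this balance and of the shifts given below can come from scaling rather than GC content. Of the calls on genes with a GC value, 65.2% held in the same direction after it and 10.3% were called in the opposite one. Counts after this adjustment are given beside the gene lists, and adjusted changes beside the genes that it moved by over 1.5 times.

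**Figure D1:**
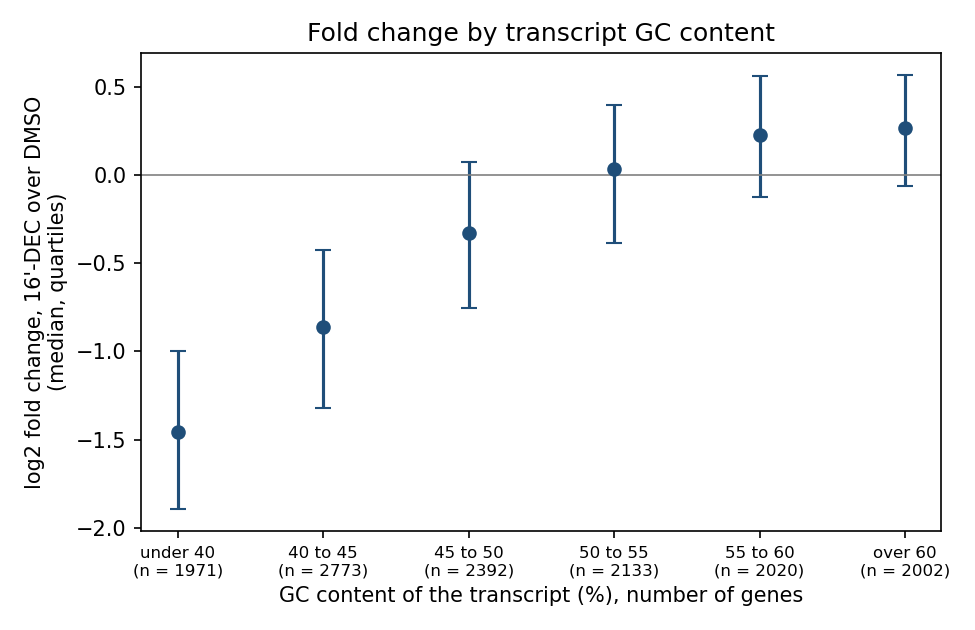
Fold change by transcript GC content: points are the median log2 fold change (16'-DEC over DMSO, vertical axis) of genes in bins of transcript GC content (percent, horizontal axis), and bars run from the lower to the upper quartile. The median rises from -1.46 in the lowest bin to 0.27 in the highest.

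Genes of the cell cycle fell as groups. In the G2/M and mitosis list, of 36 measured members 2 rose, 31 fell and 3 did not pass, with a median of -1.58. CDK1 and CENPF led the list, followed by DLGAP5, a spindle protein (38.2 ± 0.514 to 5.48 ± 0.123 TPM, -2.60, GC-adjusted -1.28), and MAD2L1, a spindle checkpoint protein (111 ± 5.74 to 20.5 ± 0.395 TPM, -2.38, GC-adjusted -1.04). PTTG1 (securin) rose by 0.28 (adjusted p = 0.0108) and CDC20, an activator of the anaphase-promoting complex, by 0.28 (adjusted p = 0.0199), although CDC20 was at -0.00418 after GC adjustment and did not pass without DMSO replicate 1 (adjusted p = 0.0616) or 16'-DEC replicate 1 (adjusted p = 0.0742). MKI67, the proliferation marker Ki-67, fell from 30.1 ± 3.23 to 7.21 ± 2.48 TPM (-1.97 ± 0.21, adjusted p = 3.89e-05, limma; -1.60 after GC adjustment). In the G1/S and DNA replication list, of 40 measured members 0 rose, 37 fell and 3 did not pass (median -0.79). RFC3 fell by 2.24 (GC-adjusted -1.04) and RFC4 by 1.54, both subunits of the clamp loader. In the DNA damage repair list, of 18 measured members 0 rose, 17 fell and 1 did not pass (median -1.46). BLM fell by 2.28 (GC-adjusted -1.16). Adjusted over the list alone, the counts of these lists were the same: 31, 37 and 17 lower. camera gave adjusted p = 2.46e-05, 2.02e-04 and 5.59e-04, but adjusted p = 0.68 with an estimated correlation for each (lowest over all alternatives 2.01e-11, 3.12e-10, 3.94e-08). Median GC contents were 43.6%, 49.4% and 42.3%, and after GC adjustment the counts were 2 higher and 30 lower, 0 higher and 32 lower and 1 higher and 15 lower, with medians of -0.77, -0.58 and -0.69.

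Regulators of the G1 phase went both ways. CDKN1A (p21) rose from 65.4 ± 5.62 to 106 ± 2.49 TPM (0.69 ± 0.0807, adjusted p = 6.46e-05, limma; 0.41 after GC adjustment), and CDK4 rose by 0.73, while CDK6 fell by 2.54 (GC-adjusted -1.19), CDKN1B (p27) by 1.00 and CCND1 (cyclin D1) by 0.95. Of the 11 CDK inhibitors and G1 cyclins measured, 4 rose and 6 fell; the median was -0.37 and turned to 0.16 with quantile normalization, and camera, which compares a list with all other genes, put it higher than these (adjusted p = 0.784), but lower after GC adjustment, with a median of -0.11. Among p53 targets, of 22 measured members 3 rose, 12 fell and 7 did not pass (camera adjusted p = 0.405): FAS, a death receptor, fell by 2.19 (GC-adjusted -0.99) and MDM2, the ligase that degrades p53, by 1.88 (GC-adjusted -0.98), while PLK3 rose by 0.77 (GC-adjusted 0.47). Among pro-apoptotic genes, of 19 measured members 8 rose, 6 fell and 5 did not pass (adjusted p = 0.142), with a median of 0.17 and a mean of -0.08; DIABLO rose by 1.01 and BID by 0.94, while FAS, also in this list, fell. Among anti-apoptotic genes, of 9 measured members 2 rose, 5 fell and 2 did not pass (adjusted p = 0.743), and 6 fell when adjusted over the list alone; BIRC2 fell by 2.01 (GC-adjusted -0.59), XIAP fell by 1.36 but was at 0.04 after GC adjustment, and BCL2L1 (BCL-XL) rose by 0.65. Tubulin genes rose, with 10 of 14 higher and 2 lower (median 0.75, camera adjusted p = 3.56e-04, adjusted p = 0.68 with an estimated correlation). TUBB3 rose by 1.08 and TUBB6 by 1.18, while TUBE1, a centriolar tubulin, fell by 1.64 (GC-adjusted -0.45). Their median GC content was 54.3%, and 11 higher and 1 lower were called after GC adjustment (camera adjusted p over all alternatives from 3.18e-06 to 0.68). After that adjustment the CDK inhibitor, p53, pro-apoptotic and anti-apoptotic lists had 3 higher and 4 lower, 4 higher and 12 lower, 10 higher and 6 lower, and 3 higher and 2 lower, and the anti-apoptotic median of -0.45 turned to 0.04. The other counts in this paragraph were the same adjusted over the list alone.

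Genes of autophagy went both ways. SQSTM1, the autophagy receptor p62, rose from 395 ± 36.3 to 1008 ± 39.3 TPM (1.35 ± 0.0814, adjusted p = 1.05e-06, limma; 1.15 after GC adjustment; ENSG00000161011, chromosome 5, 179806398 to 179838078). MAP1LC3B, which encodes the autophagosome protein LC3B, went from 184 ± 12.2 to 197 ± 11.4 TPM without passing (0.10 ± 0.0779, adjusted p = 0.256; ENSG00000140941, chromosome 16, 87383995 to 87404779); it passed with median-of-ratios scaling (0.45), quantile normalization (adjusted p = 0.0394) and after GC adjustment (0.27). ULK1, the initiating kinase, rose by 0.44 (adjusted p = 0.00638), and BECN1 (beclin 1) fell by 0.34 (adjusted p = 0.00245), but BECN1 was at 0.00452 with median-of-ratios scaling and did not pass with it, with quantile normalization or after GC adjustment (-0.02, adjusted p = 0.821). TFEB, a transcription factor of lysosomal genes, was listed at means of 3.35 and 3.41 TPM and did not pass (adjusted p = 0.891), but it passed at 0.29 with median-of-ratios scaling, 0.55 with quantile normalization and, the other way, -0.29 after GC adjustment. It also lay below 0 without DMSO replicate 1 (-0.0606) or 16'-DEC replicate 1 (-0.0498). MTOR, a kinase that restrains autophagy, had a value of -0.17 that did not pass (adjusted p = 0.0922); it passed at 0.17 with median-of-ratios scaling, was at 0.0985 with quantile normalization and -0.01 after GC adjustment, and passed at an adjusted p of 0.0423 as lower without DMSO replicate 1. In the autophagy machinery list, of 35 measured members 17 rose, 13 fell and 5 did not pass, the same counts when adjusted over the list alone. GABARAP and GABARAPL1, both relatives of LC3, rose by 0.85 and 0.98, and RB1CC1, a scaffold of the initiating complex, fell by 2.35 (GC-adjusted -0.84). The median was 0.10 and the mean -0.09, and camera did not call the list (adjusted p = 0.0685, and adjusted p = 0.68 with an estimated correlation). After GC adjustment 24 higher and 6 lower were called, with a median of 0.39 and adjusted p = 0.00402, but 0.324 with an estimated correlation beside that adjustment. The list was also called without 16'-DEC replicate 1 (adjusted p = 0.0481) or 16'-DEC replicate 3 (adjusted p = 0.0484) and with no filter on low values (adjusted p = 0.0212).

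Most lysosomal genes rose. Among lysosomal hydrolases and membrane proteins, of 38 measured members 23 rose, 5 fell and 10 did not pass (median 0.36, camera adjusted p = 5.55e-06, adjusted p = 0.68 with an estimated correlation, lowest over all alternatives 3.36e-10). CD63, a lysosomal membrane protein, rose from 277 ± 18.7 to 741 ± 27.4 TPM and the protease CTSB (cathepsin B) from 542 ± 48.9 to 1373 ± 37.9 TPM. ASAH1 (acid ceramidase) fell by 0.82 and LAMP2 by 0.63, but they were at 0.11 and 0.82 after GC adjustment. The list's median GC content was 52.7%, and 29 higher and 1 lower were called after that adjustment. Among subunits of the V-ATPase, the proton pump of lysosomes, of 16 measured members 8 rose, 5 fell and 3 did not pass, and camera did not call the list (adjusted p = 0.0854, and 0.68 with an estimated correlation). ATP6V0D1 rose by 1.23 and ATP6V0E1 by 0.69 (GC-adjusted 1.26), while ATP6V1C1 fell by 1.46 but did not pass after GC adjustment (-0.16, adjusted p = 0.105). After that adjustment 12 higher and 0 lower were called and the list was too (adjusted p = 0.00116, but 0.382 with an estimated correlation beside it), as with no filter on low values (adjusted p = 0.025). With median-of-ratios scaling alone 10 of these subunits were higher and 4 lower. Among autophagy receptors, of 14 measured members 4 rose, 8 fell and 2 did not pass (adjusted p = 0.987): CCPG1 fell by 2.07 (GC-adjusted -0.62) and TAX1BP1 by 1.51 (GC-adjusted -0.28), while SQSTM1 rose, and the list's median of -0.56 turned to 0.26 after GC adjustment (7 higher and 4 lower). Among genes of TFEB and mTORC1 feedback, of 18 measured members 3 rose, 8 fell and 7 did not pass (adjusted p = 0.878). HIF1A fell by 1.83 (GC-adjusted -0.52), PPARGC1A by 1.93 (GC-adjusted -0.71), and TFE3, a relative of TFEB, rose by 0.71. That list's median of -0.12 turned to 0.21 with median-of-ratios scaling, and after GC adjustment 5 higher and 8 lower were called. Adjusted over the list alone, the counts of these lists were 23, 8, 4 and 3 higher, as over all genes.

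**Figure D2:**
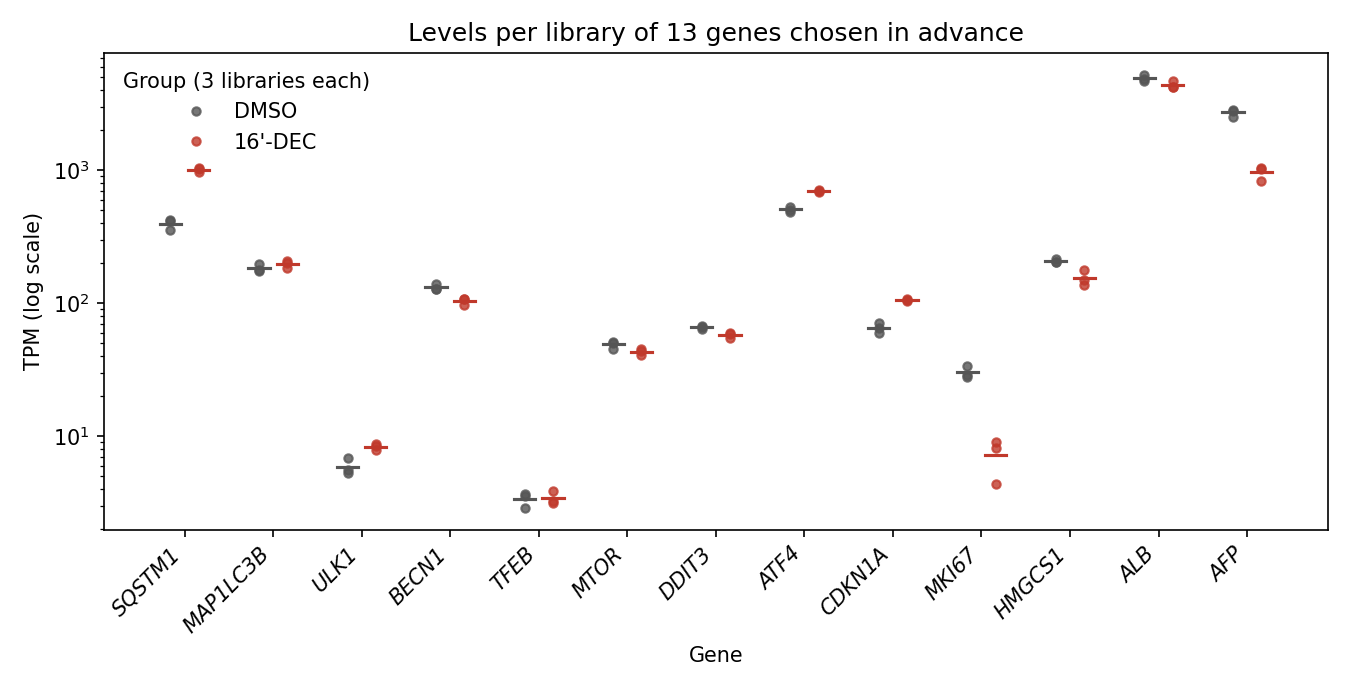
Levels of genes named in advance: each point is a library's TPM on a log axis, DMSO in grey and 16'-DEC in red (3 libraries each), and bars mark group means. SQSTM1 lies higher in all 3 libraries with 16'-DEC (1.35 on the log2 scale), and MKI67 and AFP lower (-1.97 and -1.50).

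Most genes of several stress lists rose. Among NRF2 targets, genes of the oxidative stress response, of 25 measured members 18 rose, 5 fell and 2 did not pass (median 0.74, camera adjusted p = 5.55e-06, adjusted p = 0.68 with an estimated correlation, as for every stress list that follows). AKR1C1 and OSGIN1 (1.44) led this list, and SLC7A11, the cystine transporter, fell by 1.41 but was at 0.27 after GC adjustment. Among heat shock genes, of 19 measured members 11 rose, 7 fell and 1 did not pass (adjusted p = 0.0389), and 12 rose when adjusted over the list alone. HSPA1A and HSPA1B, near-identical copies whose reads cannot be fully separated, rose from 118 ± 11.3 to 404 ± 10.2 TPM and from 108 ± 9.83 to 307 ± 2.93 TPM, while CHORDC1 fell by 1.84 (GC-adjusted -0.54). Among proteasome subunits, of 25 measured members 17 rose, 7 fell and 1 did not pass (adjusted p = 0.00126): PSMD2 rose by 1.05, PSMB7 by 1.11, and PSMA3 fell by 1.65 (GC-adjusted -0.62). Among ER chaperones and degradation factors, of 31 measured members 16 rose, 10 fell and 5 did not pass (adjusted p = 0.00359). MANF rose by 1.11, P4HB by 1.04, and ERO1A fell by 1.14 but was at 0.26 after GC adjustment. Among ATF4 and integrated stress response targets, of 31 measured members 15 rose, 8 fell and 8 did not pass (adjusted p = 0.00717). ATF4 itself rose by 0.46 (adjusted p = 1.89e-04, GC-adjusted 0.22) and PPP1R15A (GADD34) by 1.03, and CEBPG fell by 1.28 (GC-adjusted -0.54). DDIT3 (CHOP) changed by -0.19 (adjusted p = 0.0428), but was at 0.16 with median-of-ratios scaling and 0.04 with quantile normalization. Without DMSO replicate 2 or 3 or 16'-DEC replicate 1 or 2, DDIT3 did not pass (adjusted p from 0.0507 to 0.168), nor without the mean trend (0.0695).

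Immediate early genes rose as well: of 16 measured members 11 rose, 1 fell and 4 did not pass (median 0.52, camera adjusted p = 1.56e-05, and adjusted p = 0.68 with an estimated correlation). DUSP1, a phosphatase of MAP kinases, rose from 9.27 ± 0.738 to 35.7 ± 1.64 TPM and ATF3 from 6.49 ± 0.684 to 15.4 ± 1.58 TPM. MYC fell by 0.24 (adjusted p = 0.027, GC-adjusted -0.53), but was at 0.11 with median-of-ratios scaling, and it did not pass with quantile normalization (adjusted p = 0.687) or no filter on low values (0.062), nor without DMSO replicate 2 or 16'-DEC replicate 1 or 2 (adjusted p from 0.0539 to 0.0896). Among the 6 AhR targets measured, 4 rose and 1 fell (adjusted p = 0.0404, 0.68 with an estimated correlation and 0.142 after GC adjustment): CYP1A1 rose by 1.45, NQO1 by 0.86, and TIPARP fell by 0.89 but was at 0.0085 after GC adjustment. The heat shock and AhR lists were not called with median-of-ratios scaling (adjusted p = 0.134 and 0.0859), nor were the heat shock, proteasome, ER, ATF4 and AhR lists with quantile normalization (adjusted p = 0.711, 0.174, 0.146, 0.0889 and 0.174). On ranks the heat shock and AhR lists were not called either (adjusted p = 0.135 and 0.066), nor for genes with a mean of at least 5 TPM (adjusted p = 0.128 and 0.0996), and fry did not call the heat shock and ATF4 lists (adjusted p = 0.243 and 0.0987). After GC adjustment the NRF2, heat shock, proteasome, ER, ATF4, immediate early and AhR lists had 22 higher and 0 lower, 13 higher and 5 lower, 22 higher and 1 lower, 22 higher and 2 lower, 18 higher and 6 lower, 13 higher and 1 lower, and 3 higher and 1 lower, and the immediate early median was 0.32. In the same order, the lowest adjusted p over all alternatives was 7.17e-10, 0.0049, 2.20e-06, 5.58e-06, 4.47e-04, 5.67e-11 and 0.0034. Apart from heat shock, counts adjusted over the list alone were the same. Their median GC contents were 48.2%, 51.1%, 47.9%, 47.9%, 52.6%, 57% and 49.7%.

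Genes of cholesterol synthesis and uptake rose: of 24 measured members 17 rose, 4 fell and 3 did not pass (median 0.58, camera adjusted p = 7.52e-06, adjusted p = 0.68 with an estimated correlation). FDFT1 (squalene synthase) rose from 341 ± 18.5 to 774 ± 26.3 TPM and FDPS from 443 ± 29.8 to 1000.2 ± 21.2 TPM. HMGCS1, an early enzyme of the pathway, which did not pass with median-of-ratios scaling (adjusted p = 0.38), fell by 0.43 (adjusted p = 0.00299) and SC5D by 1.02, but they were at 0.76 and 0.22 after GC adjustment, when 24 higher and 0 lower were called, with a median of 0.88. Fatty acid synthesis genes were not called (adjusted p = 0.121, 0.0418 without 16'-DEC replicate 3 and 0.0447 with no filter on low values, and 0.771 with an estimated correlation; of 16 measured members 5 rose, 5 fell and 6 did not pass): ACSS2 rose by 1.29, FADS2 by 1.06, and MLXIPL (ChREBP) fell by 1.05; after GC adjustment 10 higher and 3 lower were called. In glycolysis, of 20 measured members 15 rose, 2 fell and 3 did not pass (median 0.68, adjusted p = 5.97e-06, and adjusted p = 0.68 with an estimated correlation). PKM (pyruvate kinase) rose from 417 ± 34.1 to 864 ± 44.4 TPM and PFKP from 9.43 ± 1.61 to 28.2 ± 1.84 TPM, while HK2 (hexokinase 2) fell by 0.66. Median GC contents of the cholesterol and glycolysis lists were 52% and 55.7%, and 14 higher and 2 lower of the glycolysis genes were called after GC adjustment. The lowest adjusted p over all alternatives was 1.04e-09 for cholesterol and 3.76e-10 for glycolysis, and counts adjusted over the list alone were the same.

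Cytosolic ribosomal protein genes rose: of 39 measured members 30 rose, 5 fell and 4 did not pass (median 0.68, camera adjusted p = 4.81e-09, adjusted p = 0.68 with an estimated correlation). RPL15 rose from 1807 ± 118 to 3488 ± 107 TPM, and RPL22 fell by 0.80 but was at 0.03 after GC adjustment. The list's median GC content was 51.1%, 34 higher and 2 lower were called after GC adjustment, and the call was lost with quantile normalization, which left a median of 0.36 (adjusted p = 0.174, over all alternatives from 5.48e-15 to 0.68). Among nuclear-encoded respiratory chain subunits, of 34 measured members 19 rose, 10 fell and 5 did not pass (adjusted p = 0.0221, and adjusted p = 0.68 with an estimated correlation); their median was 0.25 and their mean -0.02. UQCRC1 rose by 1.02 and COX4I1 by 0.80, while UQCRB fell by 2.22 (GC-adjusted -0.79); 25 higher and 4 lower were called after GC adjustment. The respiratory list was not called with quantile normalization (adjusted p = 0.477), on ranks (0.0577) for genes with a mean of at least 5 TPM (0.0846) or by fry, which put it lower (0.357). Counts of both lists were the same adjusted over the list alone. Of the most abundant transcripts, EEF1A1, a translation elongation factor, rose from 12159 ± 806 to 21416 ± 1209 TPM (0.82, GC-adjusted 1.31) and MT-CO2 from 11103 ± 497 to 16138 ± 933 TPM (0.54, GC-adjusted 0.89). MT-RNR2 at -0.13 (adjusted p = 0.144) and MT-CO3 at 0.04 (adjusted p = 0.587) did not pass, but MT-RNR2 was at 0.23 with median-of-ratios scaling, MT-CO3 passed at 0.39 with that scaling and was at -0.0765 with quantile normalization, and both passed as higher after GC adjustment (0.61 and 0.35). MT-ND5 fell by 0.49 and MT-ND4L by 0.49, but neither passed with median-of-ratios scaling (adjusted p = 0.316 and 0.443) or after GC adjustment (-0.04 and 0.25, adjusted p = 0.805 and 0.175). MT-ND4L (adjusted p = 0.0146) did not pass with no filter on low values either (adjusted p = 0.111), nor without DMSO replicate 1 (adjusted p = 0.0591) or 16'-DEC replicate 3 (adjusted p = 0.0596). Among mitochondrially encoded genes, of 15 measured members 2 rose, 3 fell and 10 did not pass (camera adjusted p = 0.568, higher than other genes, but lower with quantile normalization or without DMSO replicate 2; 2 fell adjusted over the list alone), and their median of -0.12 turned to 0.24 with median-of-ratios scaling. After GC adjustment 10 higher and 0 lower of them were called, with a median of 0.46, and the list was too (adjusted p = 0.00496, but 0.555 with an estimated correlation beside that adjustment). With median-of-ratios scaling alone 6 of these genes were higher and 0 lower.

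Markers of liver cells went both ways. ALB (albumin) fell from 4931 ± 260.1 to 4369 ± 242 TPM (-0.17 ± 0.0697, adjusted p = 0.0487, limma). ALB was at 0.18 with median-of-ratios scaling and 0.77 after GC adjustment. Without any 1 of the DMSO libraries or without 16'-DEC replicate 1 or 3, ALB did not pass (adjusted p from 0.0502 to 0.148), nor with a pseudocount of 5, no filter on low values, a mean of at least 5 TPM, no mean trend or array weights (0.0507 to 0.213). AFP (alpha-fetoprotein), a fetal liver protein, fell from 2721 ± 184 to 965 ± 119.8 TPM (-1.50 ± 0.0999, adjusted p = 1.88e-06), and was at -0.27 after GC adjustment (adjusted p = 0.0372). Among hepatocyte secreted proteins, of 29 measured members 11 rose, 10 fell and 8 did not pass (camera adjusted p = 0.121, median 0.08, mean -0.16): APOA2 rose by 0.72, AMBP by 0.66 (GC-adjusted 0.42), and complement C5 fell by 2.34 (GC-adjusted -1.06). Among hepatocyte transcription factors, of 16 measured members 5 rose, 6 fell and 5 did not pass (adjusted p = 0.669, median 0.07, mean -0.40). NR1H4, the bile acid receptor FXR, fell by 2.01 (GC-adjusted -0.92) and FOXA1 by 1.20, and NR0B2 (SHP) rose by 0.63 (GC-adjusted 0.34). Among fetal liver and hepatoma markers, of 12 measured members 1 rose, 7 fell and 4 did not pass (adjusted p = 0.324). EPCAM fell by 1.58 and LIN28B by 1.94 (GC-adjusted -0.49), and KRT19 rose by 1.65. Among drug metabolism genes, of 13 measured members 4 rose, 7 fell and 2 did not pass (adjusted p = 0.987), where GSTA1 fell by 1.61 (GC-adjusted -0.87) and SULT2A1 by 0.81 (GC-adjusted -0.18), and ALAS1 rose by 0.70. The drug metabolism median of -0.71 turned to 0.08 after GC adjustment. Counts adjusted over the list alone were the same for these lists. Their median GC contents were 53.7%, 54%, 48.4% and 44%, and after GC adjustment they had 15 higher and 7 lower, 5 higher and 7 lower, 1 higher and 6 lower, and 6 higher and 3 lower, with medians of 0.18 for secreted proteins and -0.01 for transcription factors.

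Targets of the Wnt pathway were mostly lower: of 13 measured members 1 rose, 11 fell and 1 did not pass, with a median of -0.59. DKK1, a secreted Wnt inhibitor, fell from 468 ± 24.9 to 132 ± 6.05 TPM (-1.82, GC-adjusted -1.18) and LGR5 from 71.3 ± 3.3 to 21.8 ± 2.66 TPM (-1.67, GC-adjusted -0.89), while GLUL (glutamine synthetase) rose by 0.57. camera did not call the list (adjusted p = 0.124, and 0.728 with an estimated correlation), but did after GC adjustment (1 higher and 12 lower, adjusted p = 3.11e-04, but 0.427 with an estimated correlation beside it) and with no filter on low values (0.00931). Among YAP and TAZ targets, of 12 measured members 1 rose, 8 fell and 3 did not pass (adjusted p = 0.209; 1 higher and 7 lower after GC adjustment): CCN2 fell by 1.05, CRIM1 by 1.19 (GC-adjusted -0.77), and AXL rose by 0.43 (adjusted p = 0.012); the list was called with no filter on low values (0.0309), but not with an estimated correlation (0.728). Counts of both lists were the same adjusted over the list alone. In all, camera called 18 of 51 lists, 15 higher and 3 lower, while another split of the 6 libraries into 3 and 3 called 20. Such a split has libraries of both groups on each side and keeps part of the difference between the groups, so it gives no chance rate. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05 (lowest adjusted p 0.165 beside GC adjustment), while fry called 29. fry does not compare a list with other genes, and the median of all tested genes was -0.31. By fry, but not camera, YAP and TAZ (adjusted p = 0.00176), Wnt (0.003), p53 (0.00176), fetal liver (8.07e-04) and anti-apoptotic lists (0.00334) were lower. So were autophagy receptors (0.003), TFEB and mTORC1 feedback (0.00502), drug metabolism (0.00298), CDK inhibitors (0.00718) and hepatocyte transcription factors (0.012).

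**Figure D3:**
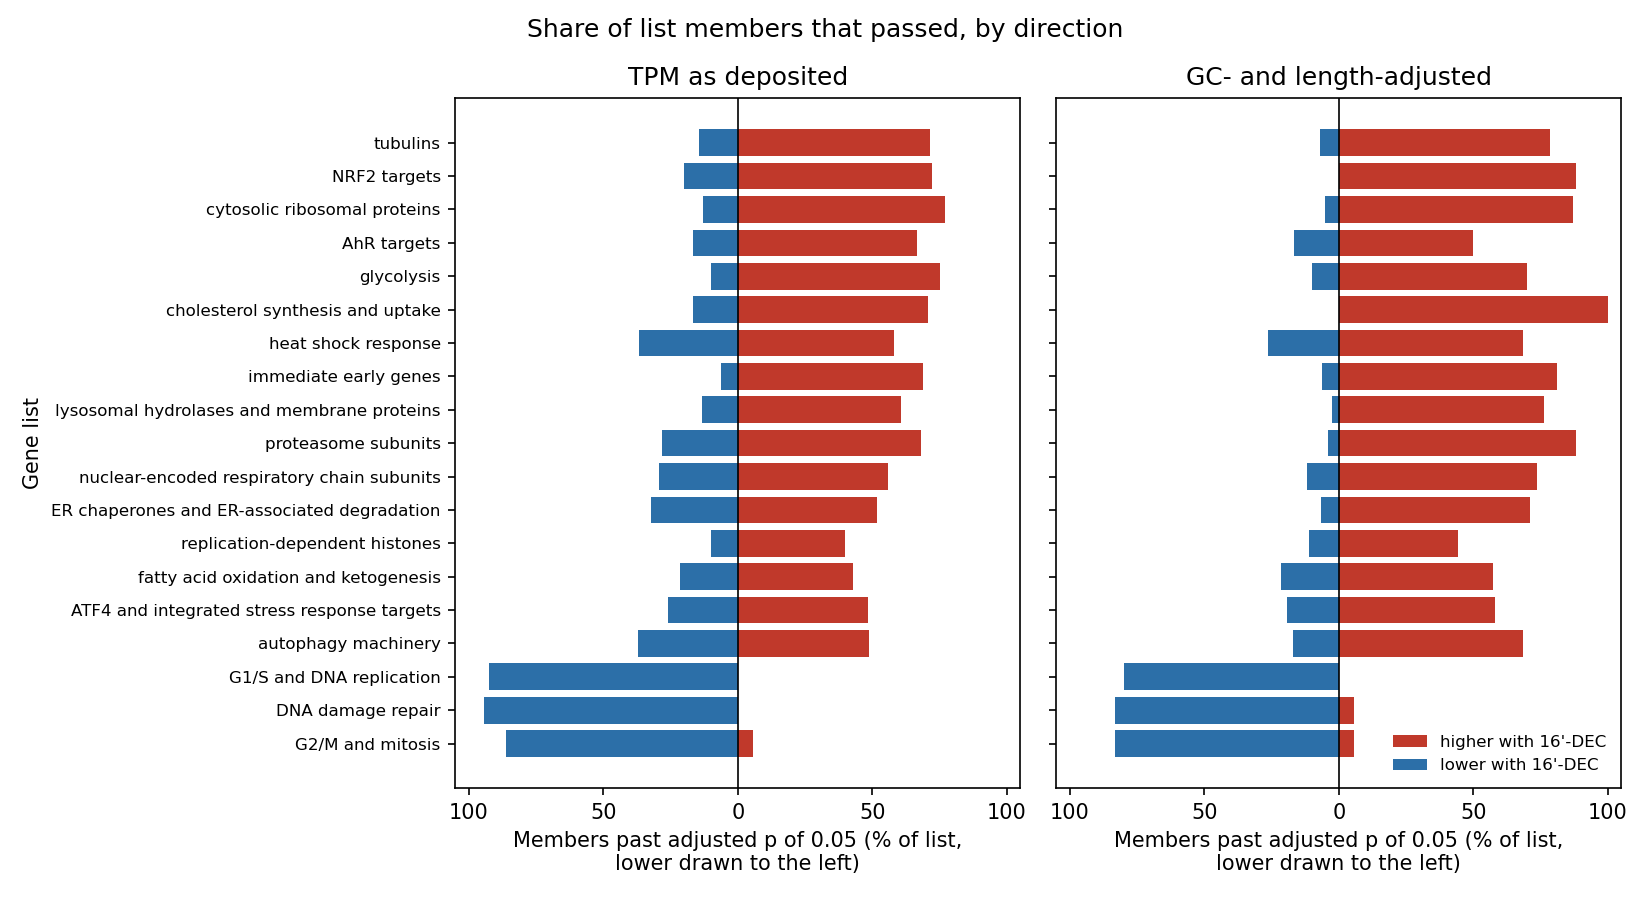
Share of list members that passed, by direction: bars give the percent of each list's measured members higher (red, right) or lower (blue, left) with 16'-DEC at an adjusted p under 0.05, for TPM as deposited (left panel) and after GC and length adjustment (right panel). G2/M and mitosis shows 31 of 36 lower as deposited, and autophagy machinery 17 higher and 13 lower.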

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

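Each of the 311 named genes and 51 tested lists was followed through every alternative in which it was tested; the adjustments for GC content and length were chosen after seeing the data. Of the values for named genes, 5678 kept direction and side of the threshold, 126 lost the call, 10 gained it and 70 turned, 6 of these called in neither fit. Most named genes were picked from the main fit by small adjusted p or large change, so their stability was partly fixed in advance. It does not stand for other genes. After GC and length adjustment 265 named genes kept direction and side, 28 turned, 14 lost the call and 2 gained it, while of all calls on genes with a GC value 65.2% held. For lists, by the direction that camera or fry gave, the numbers over all alternatives were 976, 63, 34 and 48, 43 of these called in neither. Leaving out 1 library gave 2764 to 3419 genes higher, 6556 to 6867 lower, 290 to 439 and 3198 to 3538 at least 2-fold, and 16 to 21 lists; 14 named genes changed their call without some library, and 1, TFEB, turned while called in none of these fits (-0.0606 to 0.0722). A pseudocount of 5 left 217 and 1906 genes at least 2-fold higher and lower, since it shrinks folds of low genes. Median-of-ratios scaling gave 5290 higher and 1141 at least 2-fold higher; quantile normalization gave 5990, 1246, 1873 at least 2-fold lower and 9 lists. camera with an estimated correlation called 0 lists and fry, which does not compare lists with other genes, 29. GC and length adjustment gave 4213 lower and 585 and 652 at least 2-fold higher and lower; with the replicate block these were 3981, 587 and 657. Replicate numbers did not pair the libraries (correlations of deviations 0.09, -0.18 and -0.07), and the replicate block alone gave 3014 higher, 6823 lower, 378 and 3388 at least 2-fold and 18 lists; 4 named genes did not pass with it, among them ALB and DDIT3 (adjusted p = 0.0893 and 0.0949). Beyond these constructions the cause was not tested. Absolute depth is unknown, so counting error of low genes is too.

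Log2 fold changes that turned were, with median-of-ratios scaling, BECN1 0.00452, MTOR 0.17, DDIT3 0.16, ALB 0.18, MT-RNR2 0.23, MT-ND4 0.0574, MYC 0.11; with quantile normalization, MTOR 0.0985, DDIT3 0.0375, MT-CO3 -0.0765, MMP11 0.0895, ACTA2 0.13; and after GC and length adjustment, TFEB -0.29, HMGCS1 0.76, ALB 0.77, MT-RNR2 0.61, MT-ND4L 0.25, FUNDC1 0.11, ASAH1 0.11, LAMP2 0.82, ATP6AP2 0.16, SLC38A2 0.0375, ERO1A 0.26, DNAJC3 0.0783, SC5D 0.22, STARD4 0.46, SMPDL3A 0.0424, CDC20 -0.00418, XIAP 0.0419, BCL2A1 0.25, SLC7A11 0.27, CISD1 0.43, TFRC 0.0514, MT-ND4 0.26, RPL22 0.0314, SLCO1B3 0.26, ABCB1 0.0773, UGT2B7 0.35, TIPARP 0.0085, PSMC6 0.36. The replicate block beside that adjustment left the same values, with TFEB and AFP among the genes no longer called (adjusted p = 0.0526 and 0.0642). Lists whose direction by camera turned while called in neither fit had medians there of, with no filter on low values, -0.24 (ribosome biogenesis and MYC targets), -0.0918 (bile acid synthesis and transport); for a mean of at least 5 TPM, -0.24 (ribosome biogenesis and MYC targets), -0.71 (drug metabolism genes); with median-of-ratios scaling, 0.21 (TFEB and mTORC1 feedback); and with quantile normalization, -0.39 (ferroptosis regulators), -0.33 (mitochondrially encoded genes), -0.035 (ribosome biogenesis and MYC targets), 0.19 (hepatocyte secreted proteins). They were -0.57 (autophagy receptors) without mitochondrial genes, -0.56 (autophagy receptors) without the mean trend, -0.75 (drug metabolism genes) with array weights, -0.71 (drug metabolism genes) with the replicate block, and after GC and length adjustment, with or without that block, 0.26 (autophagy receptors), -0.11 (CDK inhibitors and G1 cyclins), 0.0419 (anti-apoptotic genes), -0.12 (metallothioneins), 0.00744 (ribosome biogenesis and MYC targets), -0.0147 (hepatocyte transcription factors), 0.0773 (drug metabolism genes), -0.034 (ERK feedback targets). Without some library 4 lists turned, with medians over these fits of -0.62 to -0.50 (autophagy receptors), -0.16 to -0.0746 (mitochondrially encoded genes), -0.29 to -0.16 (ribosome biogenesis and MYC targets), -0.75 to -0.66 (drug metabolism genes). By fry the direction differed from camera for 13 lists, with medians of 0.10 (autophagy machinery), 0.26 (cytosolic tRNA synthetases), -0.37 (CDK inhibitors and G1 cyclins), 0.17 (pro-apoptotic genes), -0.27 (ferroptosis regulators), 0.25 (nuclear-encoded respiratory chain subunits), -0.12 (mitochondrially encoded genes), -0.24 (ribosome biogenesis and MYC targets), 0.0753 (hepatocyte secreted proteins), 0.0702 (hepatocyte transcription factors), -0.21 (bile acid synthesis and transport), 0.28 (urea cycle and gluconeogenesis), -0.0849 (ERK feedback targets). Their members went both ways. Among these, fry called CDK inhibitors (adjusted p = 0.00718), ferroptosis regulators (0.0191), ribosome biogenesis (0.00718) and hepatocyte transcription factors (0.012) lower. It also called LXR (0.00298), hypoxia (0.00298), TGF-beta (0.00298) and FOXO lists (0.00769) lower, which camera did not call.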

Other observations

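All tests of explanations and splits in this part were chosen after the results were seen. PLIN2, a coat protein of lipid droplets, rose from 542 ± 41.4 to 1382 ± 44.5 TPM, and ACADM, an enzyme of fatty acid oxidation, fell from 88.5 ± 3.13 to 22.4 ± 0.733 TPM (-1.93, GC-adjusted -0.92). In the list of fatty acid oxidation and ketogenesis, 6 of 14 rose and 3 fell (camera adjusted p = 0.0467, and adjusted p = 0.68 with an estimated correlation, median 0.23, with 8 higher, 3 lower and a median of 0.31 after GC adjustment). That call was also lost with quantile normalization (0.18), without the mean trend (0.0502), by fry (0.495), on ranks (0.0938), for genes with a mean of at least 5 TPM (0.128), after GC adjustment (0.103) and without any 1 of the DMSO libraries or 16'-DEC replicate 2 (0.0524 to 0.0589). ABCA1, a cholesterol exporter, fell from 23.6 ± 1.75 to 4.78 ± 1.07 TPM and LPCAT3 rose by 0.56. Among LXR targets 2 of 8 rose and 5 fell (adjusted p = 0.886, median -0.56, with 1 higher, 3 lower and a median of -0.04 after GC adjustment). SLC51B, a bile acid exporter subunit, rose by 1.53 and KLB fell by 1.20 (GC-adjusted -0.48). Among bile acid genes 4 of 11 rose and 5 fell (adjusted p = 0.562, with 5 higher, 4 lower and a median of 0.26 after GC adjustment), and their median of -0.21 turned to 0.13 with median-of-ratios scaling. HPD rose by 1.45; of urea cycle and gluconeogenesis genes 5 of 9 rose and 4 fell (adjusted p = 0.289, median 0.28, mean -0.13, with 4 higher, 4 lower and a median of -0.02 after GC adjustment). FTH1 (ferritin heavy chain) rose by 1.03 and ACSL4 fell by 1.92 (GC-adjusted -0.41). Among ferroptosis regulators 6 of 13 rose and 7 fell (adjusted p = 0.451, 0.0211 after GC adjustment and 0.382 with an estimated correlation beside it, with 10 higher, 2 lower and a median of 0.37 after GC adjustment), and their median of -0.27 turned to 0.08 with median-of-ratios scaling. MT2A rose by 1.02, the only one of 6 metallothioneins to pass (adjusted p = 0.289 for the list, 1 higher and 1 lower after GC adjustment). Counts of these lists were the same adjusted over the list alone, as were those of the lists that follow.

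NOP58 and NCL, both nucleolar proteins, fell by 2.28 (GC-adjusted -1.35) and 1.51, and ODC1 rose by 0.64. Among ribosome biogenesis and MYC targets 7 of 25 rose and 13 fell (camera adjusted p = 0.924, with 6 higher, 11 lower and a median of 0.00744 after GC adjustment), and their median of -0.24 turned to 0.11 with median-of-ratios scaling. SARS1 rose by 0.65 and NARS1 fell by 1.40 (GC-adjusted -0.77). Among tRNA synthetases 6 of 13 rose and 5 fell (adjusted p = 0.28, median 0.26, mean -0.13, with 10 higher, 2 lower and a median of 0.29 after GC adjustment). LOX fell by 2.11 (GC-adjusted -0.80) and P4HA2 rose by 1.12. Among hypoxia targets 4 of 20 rose and 11 fell (adjusted p = 0.562, median -0.60, with 7 higher, 7 lower and a median of -0.03 after GC adjustment). SKIL fell by 2.60 (GC-adjusted -0.84) and SNAI1 rose by 1.20. Among TGF-beta and mesenchymal genes 3 of 15 rose and 9 fell (adjusted p = 0.709, median -0.68, with 3 higher, 9 lower and a median of -0.29 after GC adjustment). CLDN4, a tight junction protein, rose by 1.59 and EPCAM fell by 1.58. Among epithelial junction genes 5 of 12 rose and 5 fell (adjusted p = 0.209, median 0.08, with 7 higher, 5 lower and a median of 0.55 after GC adjustment). OAS1 rose by 1.19 and IFIH1 fell by 1.79 (GC-adjusted -0.98). Among interferon genes 6 of 16 rose and 3 fell (adjusted p = 0.0767, 0.0467 without 16'-DEC replicate 3 and 0.68 with an estimated correlation, median 0.10, with 7 higher, 2 lower and a median of 0.08 after GC adjustment). NFKB2 rose by 1.11 and CCL20 fell by 1.84 (GC-adjusted -0.41). Among NF-kB genes 7 of 12 rose and 4 fell (adjusted p = 0.106, median 0.30, with 5 higher, 4 lower and a median of 0.09 after GC adjustment). LCN2 rose by 0.51 and FGL1 fell by 0.78 but was at -0.03 after GC adjustment (adjusted p = 0.661). Among acute phase genes 4 of 9 rose and 2 fell (adjusted p = 0.131, median 0.21, with 6 higher, 1 lower and a median of 0.24 after GC adjustment). DUSP5 rose by 0.99 and SPRED1 fell by 1.63 (GC-adjusted -0.23). Among ERK feedback targets 5 of 13 rose and 5 fell (adjusted p = 0.562, with 5 higher, 6 lower and a median of -0.03 after GC adjustment), and their median of -0.08 turned to 0.22 with median-of-ratios scaling. SESN1 changed by -1.50 (GC-adjusted -0.72) and TRIB1 rose by 0.57. Among FOXO targets 2 of 13 rose and 7 fell (adjusted p = 0.809, median -0.32, with 3 higher, 7 lower and a median of -0.25 after GC adjustment). TIMP1, an inhibitor of metalloproteases, rose by 1.47 and TIMP3 fell by 0.57 (GC-adjusted -0.29) but did not pass with quantile normalization (adjusted p = 0.386). Among metalloproteases and inhibitors 3 of 6 rose and 2 fell (adjusted p = 0.141, median 0.45, with 3 higher, 2 lower and a median of 0.31 after GC adjustment). With no filter on low values camera called the acute phase (0.0118), epithelial junction (0.0457) and metalloprotease lists (0.014), while with an estimated correlation the adjusted p of each was 0.68. H2AC18, a copy that shares sequence with others, rose by 1.51 and H2BC4 fell by 0.50 (GC-adjusted -0.26) but did not pass with median-of-ratios scaling or quantile normalization (adjusted p = 0.204 and 0.867). Among replication-dependent histones 4 of 10 rose and 1 fell (adjusted p = 0.0455, and adjusted p = 0.68 with an estimated correlation, median 0.23, with 4 higher, 1 lower and a median of 0.23 after GC adjustment). That call was lost with median-of-ratios scaling (0.0705), array weights (0.0695), by fry (0.259), with quantile normalization (0.146), on ranks (0.058), for genes with a mean of at least 5 TPM (0.136), after GC adjustment (0.34), without DMSO replicate 1 (0.0644) and without DMSO replicate 2 (0.0926). Poly(A) selection captures few histone transcripts.

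Markers of other cell types moved both ways. Of 10 endothelial markers 0 reached a mean of 1 TPM, of 10 fibroblast and stellate markers 2, of which ACTA2 fell by 0.34 (adjusted p = 0.0298), and of 8 markers of HeLa cells 2, CDKN2A and S100A2, which rose by 0.60 (GC-adjusted 0.28) and 0.92. ACTA2 was at 0.13 with quantile normalization and -0.01 with median-of-ratios scaling, and it passed in 1 of 6 fits without 1 library (highest adjusted p = 0.102) and not with no filter on low values (0.0862). Of the haematopoietic markers 5 did (adjusted p = 0.305 for the list, 1 higher and 1 lower after GC adjustment): CD68, also a lysosomal protein, rose from 16.8 ± 0.692 to 40.7 ± 4.93 TPM, and LYZ (lysozyme) fell from 1719 ± 86.9 to 874 ± 65.1 TPM. LYZ was at -0.07 after GC adjustment, against -0.98, and did not pass (adjusted p = 0.346).

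With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of these 1 split, the real one, reached the 10210 genes called, and the highest of the others called 0 (limma; 90 genes at an unadjusted p under 0.05, against 10512 in the real split). For genes at least 2-fold apart, 1 split reached 3753, and the highest other gave 0. For gene lists called by camera with a preset correlation, 3 splits reached 18, and the highest other called 20 lists. All splits but the real one have libraries of both groups on each side. They keep part of the difference between the groups, and the rest widens the spread within each side. Their counts of genes and lists are therefore no chance rates.

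Fold changes followed transcript GC content in all 3 treated libraries. A GC bias of the libraries that acts on every molecule alike predicts equal slopes in every class of transcript. Among genes with 1 annotated transcript, a GC content of 35% to 55% and a mean of at least 4 TPM, the slope was 1.06 ± 0.0739 log2 per 10 GC points (SE, 274 genes) in protein-coding and 0.53 ± 0.132 (119 genes) in long non-coding genes, a difference of 0.53 ± 0.151. The slope of 13 mitochondrially encoded genes, fitted without limits on GC content or TPM, lay 0.80 ± 0.325 below that of all protein-coding ones within those limits (1.12). Both differences are unlike that prediction, but they cannot decide whether such a bias is the whole cause. Non-coding transcripts are less exactly annotated, the log2(TPM + 1) scale understates changes of low genes, and the classes were not matched by level. The genes of a class are not independent replicates either. Such a bias as part of the cause cannot be told apart from the treatment, since every treated library shares the trend and long non-coding genes have a slope of 0.53 themselves. Loss of long transcripts from broken RNA as the whole cause is argued against by a rho of at least 0.559 in each of 4 classes of transcript length (highest 0.721); an effect of 16'-DEC on transcripts by GC content or a feature that goes with it stays open, untested.

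Cell cycle genes stayed lower after the GC trend was removed. After GC and length adjustment the median change was -0.77 for G2/M and mitosis and -0.58 for G1/S and DNA replication, against -1.58 and -0.79 before it. The SE of the mean, not of the median, was 0.114 and 0.0689 over members taken as independent. With their estimated correlation it was 0.198 and 0.111. After the adjustment camera called both lists (adjusted p = 2.02e-08 for each), but not with an estimated correlation (0.186 for each), while 30 of 36 and 32 of 40 members were called lower. The medians argue against the trend as the whole cause, though it may account for part of the size. Both lists were fixed before the data were examined, but the adjustment and this test were chosen after. Lower expression of these genes after 16'-DEC, apart from the GC trend, is a hypothesis tested only on these data.

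Members of the autophagy machinery list that rose and fell may have been sorted by the same GC trend as other genes. Across the 35 members, Spearman's rho of fold change against GC content was 0.751, beside 0.705 across all protein-coding genes, and it lay within the middle 95% of 10000 random lists of as many protein-coding genes (0.472 to 0.845). After adjustment 24 higher and 6 lower were called, against 20 and 11 with median-of-ratios scaling alone. A rise of these genes with 16'-DEC beside other genes of like GC content is a hypothesis that these data cannot separate from the choice of adjustment.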
